A study of Rattus norvegicus with 9 samples.

How the data were processed

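Total RNA of 9 samples of the rat cell line H9c2(2-1) was extracted with the RNeasy Plus Mini kit and sequenced on a NovaSeq X Plus instrument, per the labels' protocols. The submitters' processing notes name Salmon 1.10.3, which assigns reads to transcripts without aligning them base by base to a genome, and DESeq2, for which no version was named. Each library has 1 deposited table with 114122 RefSeq transcripts. Per the file headers, each table gives the estimated count of reads per transcript, the TPM (abundance scaled for transcript length and library total), the transcript length and the effective length. The estimated counts, as deposited, are fractional, because Salmon divides a read that fits several transcripts among them. The deposited TPM values are scaled by the authors' Salmon run to the same sum in each library. The deposited effective length is another kind of value, a number of bases: the length of a transcript as corrected by Salmon for the fragment lengths of that library, and for sequence bias where that option was used. Whether the bias options were used, and which genome build and annotation release the transcripts came from, is not given in the sources used here. No coordinates are therefore printed. Because the labels do not say that the 3 libraries of a group came from separate cultures, the p-values measure only the spread between these samples, which may be technical.

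From the deposited tables, all 114122 transcripts were matched by versioned accession to a RefSeq gene table of the assembly GRCr8, which was used for symbols, gene types and chromosome membership only. Estimated counts were summed per gene over 36856 genes and rounded to whole numbers. The totals ran from 26748673 to 48574618 per library. Genes with near-identical copies, such as ribosomal protein genes, histones and their pseudogenes, share reads that Salmon can only divide by estimate, so that their values are less certain than those of single-copy genes. Whether the counting used the strand of the reads is not given in the sources used here, so that overlapping and antisense genes may share reads too.

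The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default expression filter filterByExpr, which kept 14706 genes. All 9 libraries entered 1 model with 1 mean per group, which left 6 residual degrees of freedom, and the 3 contrasts ESW against Control, ESW against CW and CW against Control were taken from it, together with a single test over the 3 groups. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called below an adjusted p of 0.05. A secondary count used an absolute log2 fold change of at least 1. The common biological coefficient of variation was 4.84%. Levels are in CPM, reads of a gene relative to the TMM-scaled library total. For log2 CPM a prior count of 2 was used.

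The design, the alternatives, 39 gene lists with 813 genes and the rule for the named genes were fixed before the data were examined. Symbols of 5 list genes were changed to their current form, and 23 list members had no gene in the table. Lists with at least 5 tested members, 33 of the 39, were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the rotation test fry were alternatives. The rule named, per contrast, up to 8 higher and 8 lower genes with the largest changes among called genes whose libraries did not overlap and whose mean was at least 1 CPM, the 6 genes with the smallest p, up to 4 members with the smallest p of each list that passed or held at least 2 called genes, and a fixed panel of genes of oxidant defence, mitochondria and muscle. Genes with systematic names were left out of the rule, and genes low in these rankings were left out for length.

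The gene and list tests were tested on simulated counts drawn from the observed mean levels, dispersions and library sizes. In them 200 genes with a mean of at least 1 CPM were changed by known folds, and 23 further members of the NRF2 list were raised alike. These were among the 14406 genes that passed the filter. For ESW against Control, 70% of the genes with the smallest planted change of 25%, 90.4% of those changed 1.5-fold and 97.0% of those changed 2-fold were recovered, and 15 of 14183 unchanged genes were called. For ESW against CW these shares were 68.3%, 89.0% and 98.5%, with 14 of 14183 unchanged genes called. The list holding planted genes passed in both, and 0 other lists did. The simulated genes were drawn independently, whereas members of a real list can vary together (estimated correlation up to 0.53 for ribosomal proteins). The count of 0 therefore does not give the error rate of the list test in these libraries.

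Alternatives were DESeq2 size factors in place of TMM, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, offsets for the average effective transcript length of a gene in each library (for which TPM served as weights), a fit of only the 6 libraries compared, the replicate number as a block, leaving out each library in turn, and adjusted p thresholds of 0.1 and 0.01. List tests on counts corrected for average transcript length were added after the data were seen. Each contrast was set against the 10 splits of its 6 libraries, and the test over the 3 groups against 100 of the 280 splits of the 9 libraries, as was the count of genes changed in 1 group against both others, for which each split took its largest count over the 3 choices of that group. Overlap and correlation of contrasts that share libraries were also computed in 40 simulated sets of unchanged groups, with genes drawn independently.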

Results

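Gene expression was measured by RNA sequencing in H9c2(2-1) cells, a line of myoblasts from embryonic rat heart that is widely used as a cell model of heart muscle. The 9 libraries form 3 groups of 3: untreated cells (Control), cells given energized structured water (ESW) and cells given control water (CW). Both waters were given at a dilution of 0.01 for 72 h, with the medium renewed every 24 h. No duration or medium renewal is recorded for Control. The deposited tables held 39329004, 36193439 and 48574618 estimated reads in Control replicates 1 to 3. ESW replicates 1 to 3 had 36384210, 43114613 and 36103041, and CW replicates 1 to 3 had 26748673, 37503351 and 34919204. Between 13913 and 15002 genes had at least 10 reads in a library, and 14706 genes were tested.

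The cells expressed collagens and smooth muscle actin at high levels in all groups. Col1a1, a chain of type I collagen, was the gene with the most reads in every library, with 3.08% to 3.80% of the total. Myog, the regulator of muscle cell fusion and differentiation, lay at 2.86 ± 0.65 CPM in Control, 2.53 ± 0.389 in ESW and 2.41 ± 0.397 in CW. The natriuretic peptide genes Nppa and Nppb had 5 and 15 reads over all 9 libraries, and Ppargc1a and Ucp3, a coactivator of mitochondrial biogenesis and a mitochondrial carrier, had 13 and 4. These 4 genes were too low to be tested. None of the 13 mitochondrially encoded mRNAs is in the set of transcripts analysed here. Of the markers of other cell types, all 12 blood cell genes and 9 of 10 endothelial genes were under 1 CPM in every library, and Krt8, a keratin, was the highest of any such marker with up to 64.6 CPM. Markers of 5 other cell types were tested where expressed, and none was called in any contrast by edgeR.

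The first principal component held 24.1% of the variance of log2 CPM and the second 13%. The 3 ESW libraries had scores of -28.7 to -8.79 on the first component and the 3 CW libraries 15.4 to 16.5. Control replicates 2 and 3 lay at 7.08 and 12.3, next to CW, whereas Control replicate 1 lay at -10.9, within the range of ESW, and stood apart on the second component at -22.9. A single test over the 3 groups called 1409 genes (3704 at an unadjusted p under 0.05). This count was 629 with average transcript length offsets, 724 without ESW replicate 2, 398 without ESW replicate 3, 870 without CW replicate 2 and 852 without CW replicate 3.

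**Figure D1:**
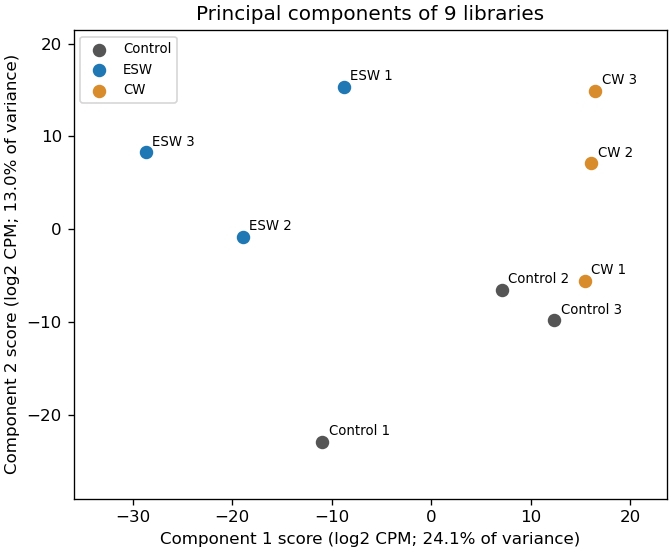
Scores of the 9 libraries on the first component (horizontal axis, 24.1% of the variance) and the second component (vertical axis, 13%) of log2 CPM; each point is a library, coloured by group. The ESW libraries lie at -28.7 to -8.79 and the CW libraries at 15.4 to 16.5 on the horizontal axis, with Control replicate 1 at -10.9.

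ESW was compared with untreated cells to ask which transcripts differ after treatment. In the lists of NRF2 targets, cholesterol and fatty acid synthesis, lysosomes and extracellular matrix the called genes were higher in ESW. In those of ribosomal proteins, proteasome subunits and respiratory complexes II to V most called genes were lower. Of these lists only NRF2 targets also passed with an estimated correlation between genes, and most members of the others were not called. The changes were small. Of 1183 called genes, 700 were higher and 483 lower, with a median absolute log2 fold change of 0.22. An absolute log2 fold change of at least 1 was reached by 26 of them, 6 higher and 20 lower. The 3 libraries of the groups did not overlap for 95.9% of the called genes and for 25.6% of all tested genes, where chance gives 10%.

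The 6 genes with the smallest p were Myh1, S100a10, Gaa, Hmox1, Lamb2 and Tgfb1. Myh1, a fast skeletal muscle myosin heavy chain, had 74.2 ± 7.13 CPM in ESW and 48.0 ± 2.09 in Control (SD, n = 3 each), a log2 fold change of 0.63 (SE 0.06, adjusted p = 3.3e-05). Gaa, the lysosomal enzyme that degrades glycogen, was 1.32-fold higher and Hmox1, the haem-degrading enzyme heme oxygenase 1, 1.35-fold higher, both with the same adjusted p of 3.3e-05. Lamb2, a laminin chain of basement membranes, rose from 270 ± 4.0 to 342 ± 7.73 CPM, and the growth factor gene Tgfb1 from 87.9 ± 3.91 to 115 ± 2.21 CPM. S100a10, the partner of annexin A2, fell from 250 ± 5.77 to 195 ± 4.50 CPM. Its relative S100a6 was lower at 385 ± 22.3 against 609 ± 108 CPM, with a log2 fold change of -0.66 (adjusted p = 0.00042).

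Among the genes that the rule names for the largest changes, at a mean of at least 1 CPM, Mmp2 was 1.85-fold higher at 4.01 ± 0.483 CPM. Mmp2 is the gelatinase A that cleaves type IV collagen. Scn4a, the sodium channel of skeletal muscle, and Osgin1, an oxidative stress response gene, were higher by 0.81 on the log2 scale each. Among the genes that the rule names the largest fall was that of the histone gene Hist1h2an, with a log2 fold change of -1.09 (SE 0.18), followed by Mlnr at -0.90 and Rps23l1 at -0.69. Reads of Hist1h2an and Rps23l1 can be shared with near-identical copies.

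Of the 33 fixed lists, 12 passed camera with the preset correlation, 8 upward and 4 downward. NRF2 targets, the genes of glutathione, NADPH and iron handling that the transcription factor NRF2 drives, had the highest median, a log2 fold change of 0.17. In this list 14 of 24 members were higher, 0 lower and 10 not called, and 16 were higher when adjusted over the list alone (camera adjusted p = 8e-11). It was the list that also passed with an estimated correlation, with an adjusted p = 0.0107. Besides Hmox1, the ferritin light chain gene Ftl1 rose from 2383 ± 125 to 3076 ± 177 CPM. Pgd, phosphogluconate dehydrogenase, was higher by 0.23 on the log2 scale (adjusted p = 0.0016).

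Of 23 genes of cholesterol synthesis, 11 were higher, 0 lower and 12 not called (16 higher when adjusted over the list alone), with Lss and the regulator Srebf2 at log2 fold changes of 0.30 and 0.21. For this list camera gave an adjusted p = 8e-11, and the adjusted p was 0.371 with an estimated correlation. Of 12 genes of fatty acid synthesis, 5 were higher, 0 lower and 7 not called (6 higher when adjusted over the list alone). They included Acss2, an acetyl-CoA synthetase, at 0.31 and Acly, ATP citrate lyase, at 0.17, and the adjusted p was 5.6e-05 with the preset and 0.371 with an estimated correlation. In the citric acid cycle 3 of 19 genes were higher, 0 lower and 16 not called (3 higher when adjusted over the list alone): Ogdh, Pc and Mdh2 at 0.18, 0.24 and 0.15. The adjusted p was 0.0469 with the preset and 0.429 with an estimated correlation.

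Lysosomal and autophagy genes showed 10 of 24 members higher, 0 lower and 14 not called (11 higher when adjusted over the list alone). The proteases Ctsd and Ctsb were higher by 0.24 and 0.22 on the log2 scale. The adjusted p was 5.6e-10 with the preset and 0.102 with an estimated correlation. In the extracellular matrix list 9 of 30 genes were higher, 0 lower and 21 not called (13 higher when adjusted over the list alone). Col1a1 lay at 38336 ± 927 CPM in ESW and 31332 ± 1033 in Control, and Col1a2 and elastin (Eln) had log2 fold changes of 0.22 and 0.30. The adjusted p was 2.6e-09 with the preset and 0.371 with an estimated correlation.

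Among targets of YAP and TGF-beta, 4 of 19 were higher, 0 lower and 15 not called (4 higher when adjusted over the list alone). Tgfb1 led, followed by Ltbp2, which binds latent TGF-beta, at 0.26. In the list of smooth muscle genes and targets of the serum response factor 3 of 14 were higher, 0 lower and 11 not called (8 higher and 1 lower when adjusted over the list alone). Acta2, smooth muscle actin, rose by 0.17 and Smtn, smoothelin, by 0.18. Both lists lost their calls with an estimated correlation (adjusted p = 0.0014 and 0.00022 with the preset, adjusted p = 0.429 each with the estimate). Heat shock genes had 3 members higher and 1 lower of 16 and did not pass (adjusted p = 0.0604). The 3 were Hspb1, Bag3 and Hspa1b, and the mitochondrial chaperone Hspe1 was lower, at -0.22.

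The lower list with the smallest p was that of cytosolic ribosomal proteins, with 16 of 57 genes lower, 0 higher and 41 not called (22 lower when adjusted over the list alone) and a median log2 fold change of -0.10. Rpl9, Rps25 and Rps18 had values of -0.41, -0.23 and -0.33. The adjusted p was 2.6e-10 with the preset and 0.430 with an estimated correlation. Of 27 proteasome subunits 7 were lower, 1 higher and 19 not called (9 lower and 1 higher when adjusted over the list alone). Psma6 and Psmb1 of the core particle fell by 0.32 and 0.34, and Psmd2 of the regulatory particle rose by 0.16. The adjusted p was 0.00031 with the preset and 0.429 with an estimated correlation. Of 39 subunits of complexes II to V, 7 were lower, 1 higher and 31 not called (12 lower and 2 higher when adjusted over the list alone), with Cox7b at -0.32 and Atp5pb at -0.21. Of 23 G2/M genes 2 were lower, Birc5 and Hmmr at -0.29 and -0.24, 0 higher and 21 not called (6 lower when adjusted over the list alone). These 2 lists had an adjusted p of 0.0014 and 0.0013 with the preset, and adjusted p = 0.575 and 0.441 with an estimated correlation. The mean log2 CPM of these 4 lower lists did not separate the libraries: ESW replicate 1 lay above Control replicate 1 for ribosomal proteins (8.24 against 8.19), for the proteasome (6.990 against 6.988) and for complexes II to V (6.84 against 6.80), and ESW replicate 3 above Control replicate 3 for G2/M genes (6.39 against 6.36).

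In the fixed panel, Hmox1 and Nqo1, a quinone reductase, were called higher, Nqo1 by 0.23 (adjusted p = 0.0053). Superoxide dismutases 1 and 2 had log2 fold changes of -0.03 and 0.02 for Sod1 and Sod2 (SE 0.04 and 0.05; adjusted p = 0.739 and 0.876). The values for Cat, Gpx1, Tfam, Ucp2 and Myog were 0.13, -0.12, -0.13, 0.33 and -0.17, with adjusted p from 0.0831 to 0.640. Nfe2l2, which encodes NRF2, was at -0.02 and its repressor Keap1 at 0.16 (adjusted p = 0.873 and 0.139). The extracellular Sod3 outside this panel was higher by 0.36, whereas Gpx8 and Prdx4, peroxidases of the endoplasmic reticulum, were lower, at -0.27 and -0.26; scavenging enzymes as a list had 1 higher and 2 lower of 21 and did not pass (adjusted p = 0.0903).

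**Figure D2:**
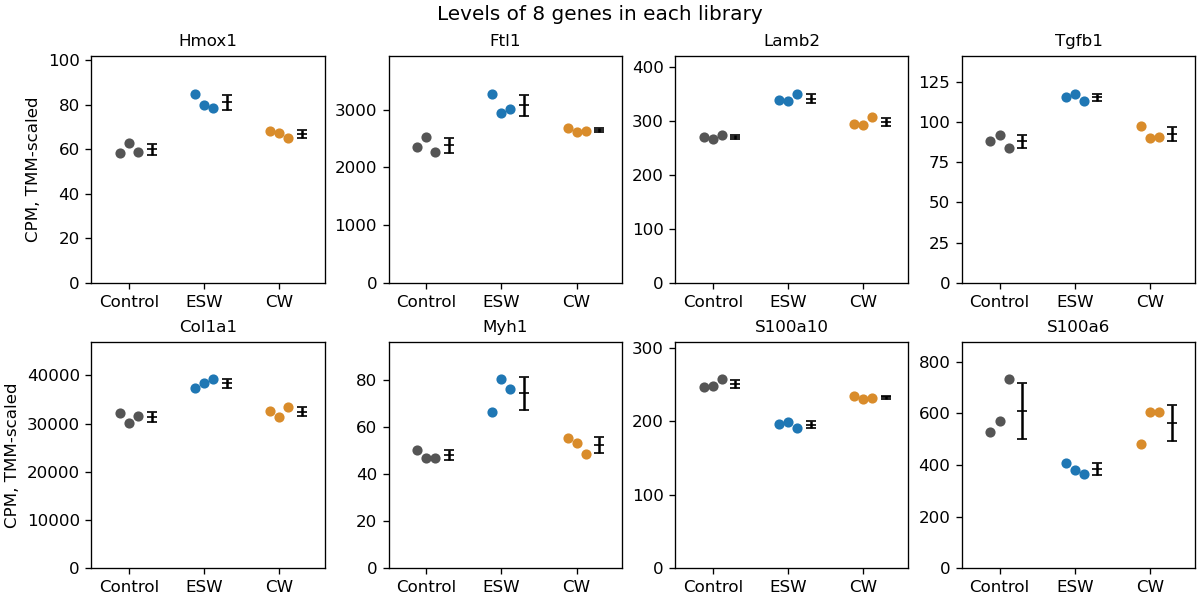
Levels of 8 genes (vertical axes, TMM-scaled CPM from 0) in the 3 groups; each coloured point is a library, and the black marks give the mean ± SD (n = 3). In each panel the 3 ESW libraries lie on 1 side of all others, for example Hmox1 at 81.1 ± 3.31 CPM against 59.9 ± 2.48 in Control and 66.8 ± 1.66 in CW. The 8 genes were picked from those called in ESW against Control, so that the separation follows in part from the choice. The libraries of ESW and Control did not overlap for 25.6% of all tested genes.

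With offsets for the average effective length of each gene's transcripts 440 genes were called, of which 410 were among the 1183, and 1181 of the 1183 kept their sign. Of the genes named here Scn4a, Osgin1, Mlnr, Rps23l1, Atp5pb, Srebf2, Ogdh, Mdh2, Smtn, Hspa1b, Gpx8, Birc5 and Hmmr lost their calls under these offsets. The count was 534 without Control replicate 2, 590 without Control replicate 3 and 397 without ESW replicate 3. The division into higher and lower genes moved too. It was 776 and 754 without a filter on low counts, 782 and 762 without Control replicate 1, and 856 and 470 with DESeq2.

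ESW was compared with CW to set the treated water against water as such. In the lists of extracellular matrix, smooth muscle, lysosomal and NRF2 target genes the called genes were again higher in ESW, and in those of ribosomal proteins and the proteasome most called genes were lower. Of these lists only NRF2 targets also passed with an estimated correlation, and in most lists the majority of members was not called. The median of long non-coding RNAs was lower. Of 1197 called genes 610 were higher and 587 lower, with median folds of 1.14 and 0.774. An absolute log2 fold change of at least 1 was reached by 5 higher and 66 lower genes. Among 1708 tested lncRNA genes 2 were higher and 142 lower, and their median log2 fold change was -0.31, against 0.01 for 12914 protein-coding genes.

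The 6 genes with the smallest p that the rule named were Zfp709l1, Myh1, Pnn, Mgll, Tmem64 and Eln. Zfp709l1, a zinc finger gene, had 14 ± 0.0867 CPM in ESW and 22.6 ± 0.573 in CW (SD, n = 3 each), a log2 fold change of -0.70 (SE 0.08, adjusted p = 0.00037). Myh1 was 1.42-fold higher (adjusted p = 0.00041). Pnn, pinin, a protein of nuclear speckles and cell junctions, was lower, at -0.41. Mgll, the lipase of monoacylglycerols, was higher by 0.49 and Tmem64 by 0.59. Elastin (Eln) rose from 375 ± 25.2 to 482 ± 18.4 CPM.

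Of the genes that the rule named for the largest rises, Tmem276-zftraf1 was at 3.23 ± 1.3 CPM against 0.371 ± 0.642. It is a readthrough gene that shares sequence with its neighbours. The pseudogene Hsp90aa1-ps17 was higher by 1.07 on the log2 scale, at 51.0 ± 18.0 against 24.2 ± 12.1 CPM. Both can share reads with their relatives. Other higher genes were Sfxn5, a mitochondrial carrier, at 0.60 and Kcng1, a potassium channel subunit, at 0.51. Lower were Vof16 at -1.42, Gnb3, a G protein subunit, at -1.25, Sap25 at -1.21 and Snorc at -1.18. In ESW Gnb3, Sap25 and Snorc lay at only 0.605, 0.611 and 0.642 CPM. Vof16 had 117 reads in ESW replicate 1 but 46 and 33 in replicates 2 and 3, and its mean was 1.78 ± 1.32 CPM. The value of Snorc changed sign, to 0.40, with average transcript length offsets (adjusted p = 0.697).

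Of 33 lists 11 passed, 9 upward and 2 downward. NRF2 targets had 10 of 24 members higher, 0 lower and 14 not called (12 higher when adjusted over the list alone). The list had a median of 0.13, and it was the list that also passed with an estimated correlation, with an adjusted p = 0.0384. Hmox1 and Ftl1 were higher by 0.28 and 0.22. In the extracellular matrix list 11 of 30 genes were higher, 0 lower and 19 not called (17 higher when adjusted over the list alone), with Col1a1, Col1a2 and Col3a1 at 0.24, 0.21 and 0.22. In the smooth muscle list 7 of 14 were higher, 0 lower and 7 not called (10 higher when adjusted over the list alone), including Acta2 at 0.17 and Cnn1, calponin, at 0.17. Of 19 YAP and TGF-beta targets 5 were higher, 0 lower and 14 not called (9 higher when adjusted over the list alone), led by Tgfb1 at 0.32 and Ltbp2 at 0.24. These 3 lists had an adjusted p of 9e-10, 9.7e-08 and 7.7e-06 with the preset, and adjusted p = 0.302 each with an estimated correlation.

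Lysosomal genes had 7 of 24 members higher, 0 lower and 17 not called (9 higher when adjusted over the list alone), with Ctsb and Ctsd at 0.20 and 0.19; the adjusted p was 9.7e-08 with the preset and 0.189 with an estimated correlation. Heat shock genes had 3 higher, 1 lower and 12 not called of 16 (4 higher and 1 lower when adjusted over the list alone), with Bag3 at 0.22, Hspa1b at 0.49 and Hspe1 at -0.21. In the citric acid cycle Idh3a and Ogdh at 0.16 and 0.18 were the 2 called of 19 (6 higher when adjusted over the list alone). These 2 lists had an adjusted p of 0.0099 and 0.0234 with the preset, and adjusted p = 0.40 each with an estimated correlation. In cholesterol synthesis 2 of 23 were higher, Ebp at 0.31 and Srebf2 at 0.14 (4 higher when adjusted over the list alone), and in fatty acid synthesis 1 of 12, Acss2 at 0.24 (1 higher when adjusted over the list alone). Their adjusted p of 0.0058 and 0.0080 rose to an adjusted p of 0.573 and 0.473 with an estimated correlation.

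On the lower side, 12 of 57 ribosomal protein genes were lower, 0 higher and 45 not called (16 lower when adjusted over the list alone), with Rpl9 at -0.33 and Rps18 at -0.32. Of 27 proteasome subunits 5 were lower, 1 higher and 21 not called (8 lower and 1 higher when adjusted over the list alone), with Psma6 at -0.25. In the mean log2 CPM of both lists ESW replicate 1 lay above CW replicate 1 (8.24 against 8.21 and 6.99 against 6.98). The adjusted p was 1.8e-08 and 0.0102 with the preset, and adjusted p = 0.566 each with an estimated correlation. Subunits of complexes II to V had 6 lower and 1 higher of 39 and did not pass as a list (adjusted p = 0.220). Of p53 targets, the cell cycle inhibitor Cdkn1a and Phlda3 were higher by 0.26 and 0.16, and the list did not pass (adjusted p = 0.303).

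In the panel Hmox1 and Nqo1 were called, at 0.28 and 0.18 (adjusted p = 0.0018 and 0.0215). Sod1, Sod2, Cat, Gpx1, Nfe2l2, Keap1, Tfam, Ucp2 and Myog were not called, with log2 fold changes of 0.01, 0.02, 0.12, -0.19, 0.05, 0.03, -0.16, 0.09 and 0.05 and adjusted p from 0.0744 to 0.904. With average transcript length offsets 802 genes were called, 732 of them among the 1197, and Sfxn5, Tmem64, Sap25, Snorc, Idh3a and Ogdh lost their calls. The count was 571 without ESW replicate 2, 314 without ESW replicate 3, 407 without CW replicate 2 and 474 without CW replicate 3.

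**Figure D3:**
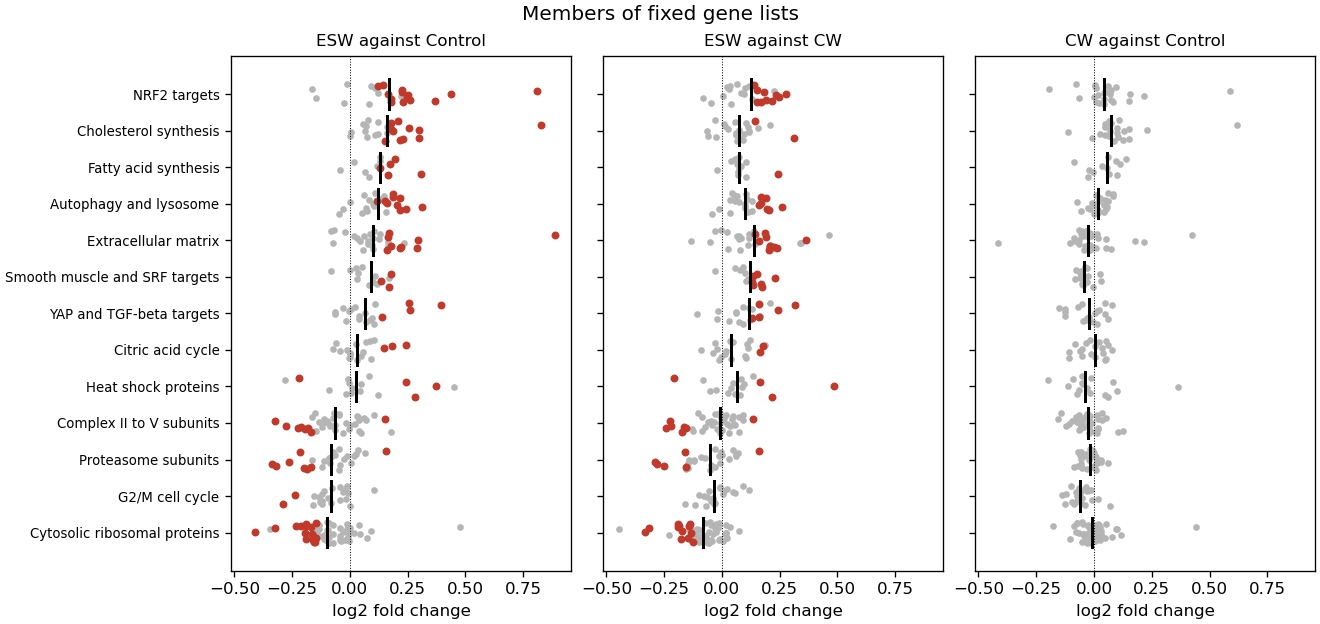
Log2 fold changes (horizontal axes) of the tested members of the 13 lists that passed camera in a comparison of ESW, in the 3 contrasts; each point is a gene, red where its adjusted p is under 0.05 and grey otherwise, and the black bar is the median of the list. The median of NRF2 targets is 0.17 against Control and 0.13 against CW, and that of ribosomal proteins -0.10 and -0.08.

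CW was compared with Control to see what water without the energizing step does. Few genes differed: 26 were called, 4 higher and 22 lower. The 4 higher genes were all non-coding RNAs. Of these the rule named Rn28s, the 28S ribosomal RNA, at 3906 ± 145 CPM in CW and 3093 ± 149 in Control (log2 fold change 0.34, SE 0.05, adjusted p = 0.0067), and Rn7sl1, the RNA of the signal recognition particle, at 14.8 ± 7.48 against 6.30 ± 0.677 CPM (adjusted p = 0.0315). The others, named after their values were seen, were the ribosomal RNA gene LOC120093067 at 0.97 and the lncRNA LOC134479817 with 5.86 ± 3.15 CPM in CW, 0.199 ± 0.344 in Control and 0 in all 3 ESW libraries. Ribosomal and signal recognition particle RNA thus differed between the libraries of CW and Control.

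Among the lower genes, Tceal8, a transcription elongation factor-like gene, was at 117 ± 1.55 CPM against 149 ± 3.95, a log2 fold change of -0.35 (adjusted p = 0.0014). Lypla1, which removes palmitate from proteins, Sh3bgrl1, and Prrg1, a membrane protein with a Gla domain, were lower, at -0.30, -0.31 and -0.42 (adjusted p = 0.0016, 0.0034 and 0.0062). H3f3a, a gene of the replacement histone H3.3, was at -0.26, and Fundc1, a receptor of mitophagy, at -0.36. Eef1a1l1, a copy of an elongation factor gene that can share reads with its relatives, was at -0.56. Rnf138 and Mzt1 were at -0.33 and -0.30.

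Of 33 lists 6 passed with the preset correlation and 0 with an estimated one, and 0 members of these 6 lists were called over all genes. Cholesterol synthesis and NRF2 targets were upward, with medians of 0.07 and 0.04, and 4 of 23 and 2 of 24 members higher when adjusted over the list alone (adjusted p = 5e-07 and 0.0183 with the preset, adjusted p = 0.895 and 0.297 with an estimated correlation). G1/S and G2/M genes were downward with medians of -0.05 and -0.06, with 2 and 0 members lower when adjusted over the list alone (adjusted p = 0.0076 and 0.0045 with the preset, adjusted p = 0.297 and 0.896 with the estimate). Subunits of complexes II to V and smooth muscle genes were downward with medians of -0.03 and -0.04, with 1 and 0 members lower when adjusted over the list alone (adjusted p = 0.0331 and 0.0348 with the preset, adjusted p = 0.896 each with the estimate). No gene of the panel was called: Hmox1 was at 0.16 (adjusted p = 0.230), Ucp2 at 0.24, Keap1 at 0.12, Gpx1 at 0.07, Nqo1 at 0.05, Tfam at 0.03, Cat at 0.01, Sod1 at -0.04, Nfe2l2 at -0.06 and Myog at -0.23, and Sod2 had 50.6 ± 1.79 against 50.6 ± 1.81 CPM. At an unadjusted p under 0.05 there were 1452 genes by edgeR, where chance gives 735.3. With average transcript length offsets 2 genes were called, LOC120093067 and LOC134479817, and all genes that the rule names in this comparison lost their calls. DESeq2 called 78 genes, 273 were called without a filter on low counts and 16 in the fit of only the 6 libraries compared. The count was 17, 13 and 51 without Control replicates 1, 2 and 3 and 14, 11 and 5 without CW replicates 1, 2 and 3.

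The comparisons of ESW with Control and with CW had 616 genes in common with the same direction, 381 higher and 235 lower. Of NRF2 targets, 10 of 24 were higher in both; of extracellular matrix genes, 8 of 30; of lysosomal genes, 7 of 24. Of ribosomal protein genes 10 of 57 were lower in both, of proteasome subunits 5 of 27 and of complexes II to V 6 of 39. Cholesterol synthesis had 2 of 23 higher in both. The mean log2 fold change of that list was 0.176 in ESW against Control and 0.0745 in ESW against CW. In CW against Control, which shares the Control libraries, it was 0.102, so that part of the rise over Control was also present in CW. The 2 genes called in opposite directions, named after their values were seen, were Tceal8 and LOC120093067, and both were also called in CW against Control.

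Because the 2 comparisons share the ESW libraries, they are related by chance. In 40 simulated sets of unchanged groups the shared count was 0.075 on average and at most 1. These sets had only 0.775 and 1.125 called genes on average in the 2 comparisons. Their shared count was therefore bound to be near 0, and it does not give the overlap expected of 1183 and 1197 calls. Independent lists of these sizes would share 29.0 higher and 19.3 lower genes. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.69, against 0.50 in the simulations. The covariance was 0.0669, against 0.0212 in the simulations, a difference of 0.0456, and over genes of at least 10 CPM it was 0.0114 against 0.00213. The 3 ESW libraries cannot be divided into parts of at least 2, so that part of the excess may come from the shared libraries. The shared count was 270 with average transcript length offsets, 337 and 342 without Control replicates 2 and 3, 339 and 150 without ESW replicates 2 and 3, and 256 and 292 without CW replicates 2 and 3. ESW against Control and CW against Control, which share the Control libraries, had 10 genes in common, 1 higher and 9 lower. Independent lists would share 0.190 higher and 0.723 lower. The simulations shared 0.125 on average, again bound to be near 0, with 0.85 called genes on average in CW against Control. The log2 fold changes of these 2 comparisons correlated at 0.27, against 0.48 in the simulations (0.31 against 0.49 over genes of at least 10 CPM). The same sign was found for 60.9% of genes, against 66.2%. Their covariance was 0.0197, against 0.0203 in the simulations, and over genes of at least 10 CPM 0.00319, against 0.00208.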

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

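List tests on counts corrected for average transcript length were chosen after the data were seen; all other alternatives were set before. The 5 gene counts (ESW against Control, ESW against CW, CW against Control, the 3 groups, and ESW against both) were 1945, 2054, 44, 2197 and 1097 at an adjusted p under 0.1 and 415, 345, 9, 425 and 173 under 0.01. With average transcript length offsets they were 440, 802, 2, 629 and 270; 410, 732 and 2 of the main calls remained in the 3 contrasts, and 2, 3 and 0 of them changed sign. The median size of the called log2 fold changes moved from 0.22 to 0.19 for ESW against Control from 0.23 to 0.22 for ESW against CW and from 0.29 to 0.17 for CW against Control; why the remaining calls ended was not tested. Of the called genes the rule names, 37 of 96, 23 of 81 and 11 of 11 lost their calls with these offsets. Of these genes Snorc alone turned its direction, in ESW against CW, to 0.40, and to 0.36 with the block added. For CW against Control the count was 273 without a filter, 78 with DESeq2 and 16 in a fit of only the 6 libraries; the cause was not tested. DESeq2 size factors, the filter of 1 CPM and limma-voom kept every one of the 5 counts within 1.5 times, and no scaling moved the median of all genes by 0.1.

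Leaving out 1 library at a time gave 397 to 1544 genes for ESW against Control, 314 to 1486 for ESW against CW, 5 to 51 for CW against Control, 398 to 1662 for the 3 groups and 150 to 904 for ESW against both. The lowest counts came without ESW replicate 3, or without CW replicate 3 for CW against Control, and the highest without Control replicate 1, or Control replicate 3 for CW against Control. No main call of a contrast changed sign in these fits, which hold fewer samples. Of the 96 and 81 called named genes, 42 and 24 kept their calls and direction in all alternatives.

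The lists past the threshold were 12, 11 and 6, and 1, 1 and 0 with an estimated correlation, which allows for genes of a list varying together. The test fry gave 12, 9 and 1, but not the same lists. In ESW against Control ribosomal proteins, proteasome, complexes II to V and G2/M genes did not pass fry (adjusted p = 0.125, 0.0766, 0.229 and 0.173). Glycolysis, hypoxia, G1/S and heat shock lists passed it instead. In ESW against CW ribosomal proteins, proteasome, cholesterol and fatty acid synthesis did not pass fry (adjusted p = 0.201, 0.201, 0.208 and 0.0695), whereas glycolysis and hypoxia did. Counts corrected for average transcript length gave 15, 13 and 6, with 12, 11 and 5 of the main lists among them. Without 1 library CW against Control had 3 to 9 lists.

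No pairing of the samples by the replicate numbers that the groups share was seen in expression. The 9 same-number pairs had correlations of deviations of -0.118 to 0.0402, 0 of them over 0.1, and 1 of 9 libraries correlated best with its own number. Such correlations cannot show whether samples of the same number were handled together. With the number as a block the counts were 971, 949, 25, 1088 and 481, and with the block and average transcript length offsets 256, 487, 2, 263 and 150. The block left 12, 11 and 6 lists. At these depths 70% of planted changes of 25% were recovered in simulated data for ESW against Control.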

Other observations

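The tests with average transcript length offsets, the gene counts over splits of 6 libraries, the form of the 9-library split test for genes changed in 1 group against both others and the counts on chromosome X were chosen after their results, or results bearing on them, had been seen; the other tests were set before. Among the 1708 tested lncRNA genes, 2 were higher and 53 lower in ESW against Control and 2 higher and 142 lower in ESW against CW, with median log2 fold changes of -0.21 and -0.31. In CW against Control 1 lncRNA gene was higher and 1 lower. Against Control the share called lower in ESW was 3.10% of lncRNA and 3.31% of protein-coding genes, and against CW 8.31% and 3.38%. The share called higher was 0.117% of lncRNA genes in both, against 5.40% and 4.70% of protein-coding genes. Other non-coding classes were also lower in ESW against CW: 3 of 6 ribosomal RNA genes were called lower (median -0.23), the signal recognition particle RNA Rn7sl1 was at -1.02 and the median of 53 transcribed pseudogenes was -0.19. Against Control the same medians were 0.16 for ribosomal RNA and -0.17 for pseudogenes, and Rn7sl1 was at 0.19, so that ribosomal RNA and Rn7sl1 did not follow the lncRNAs there. The lncRNA genes took 0.682% to 0.719% of all reads in the 3 ESW libraries, 0.774% to 0.877% in Control and 0.849% to 0.878% in CW. In ESW against CW the nuclear speckle gene Pnn was at -0.41 and, picked after its value was seen, the cyclophilin-related gene Nktr at -0.48 (adjusted p = 0.00045 and 0.00083).

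Osmotic response genes held 3 higher and 1 lower of 15 in both comparisons of ESW. The taurine and amino acid transporters Slc6a6 and Slc38a2 were higher by 0.18 and 0.12 against Control and by 0.18 and 0.16 against CW. The lower gene was not the same: the water channel Aqp1 at -0.24 against Control and Nfat5 at -0.23 against CW. The list did not pass (adjusted p = 0.0604 and 0.220). Glycolysis genes went both ways in ESW against Control, with 4 higher and 2 lower of 18 (Aldoa at 0.22, Gpi at 0.17, Tpi1 at -0.23); the list's median was 0.04 and its mean -0.07, and it did not pass (adjusted p = 0.258). Hypoxia targets had 1 higher and 3 lower of 16, among them Bnip3 at -0.26 (adjusted p = 0.427 for the list). Skeletal muscle genes had a median of -0.09 and a mean of 0.03, with Myh1 and titin (Ttn, 1.13 ± 0.118 against 0.494 ± 0.165 CPM) called higher (adjusted p = 0.427 for the list).

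The rise of NRF2 targets in ESW against Control was weighed against a sequence or length bias between libraries and against differences in proliferation. Effective lengths and fold changes were related across genes (rank correlation 0.304, which fell to 0.0329 with the offsets; genes are not independent replicates), but for 4250 genes with a single transcript the correlation of 0.347 fell only to 0.177. With average transcript length offsets the median of the 24 members was 0.16 (95% bootstrap interval over members 0.11 to 0.23), against 0.17 without, which argues against the part of the bias that the offsets removed as the whole source; the part that remained stays open. With the level of the G2/M list as a covariate the median was 0.19 (0.14 to 0.26). The slope of this covariate, fitted beside the group means, rests only on differences between libraries within groups. The interval over members leaves out the error of that slope. The fit therefore cannot decide on a difference in proliferation, which stays open. That ESW itself raises these genes remains a hypothesis. The labels record medium renewal for ESW and CW but not for Control, and no differences in harvest or extraction. Differences in culture, harvest or extraction between the groups therefore stay open.

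The lower lncRNA level in ESW against CW was weighed against low expression, bias, and less non-coding or unprocessed RNA in general. The median of -0.31 lay below all 10000 lists of protein-coding genes matched on mean expression, whose medians had a 95% range of -0.10 to -0.07, which argues against low expression as the whole source. With average transcript length offsets it was -0.31 (95% bootstrap interval over members -0.33 to -0.29). But the offsets turned the rank correlation of length and fold change from 0.0866 to -0.127, so that a bias between libraries stays open. Within protein-coding genes, non-coding transcript models took 0.342% ± 0.0176 of the reads in ESW, 0.387% ± 0.0237 in Control and 0.419% ± 0.0105 in CW (SD, n = 3 each), a difference of -0.0772 percentage points between ESW and CW with no overlap. A lower share of non-coding or unprocessed RNA in the ESW libraries may therefore be part of the source and stays open, whether from extraction or from the cells, although ribosomal RNA and Rn7sl1, which are not unprocessed RNA, were lower against CW only.

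The lower level of ribosomal protein mRNAs in ESW against Control was weighed against short transcripts, bias and a single library. With offsets the median of 57 genes was -0.0923 (95% bootstrap interval over members -0.12 to -0.05), against -0.0978 without. The members vary together (estimated correlation 0.53), so that this interval does not measure the spread between libraries. With 1 library left out at a time the median stayed at -0.0715 or lower (nearest 0 without ESW replicate 3). These medians argue against the part of the bias that the offsets removed and against 1 library as the whole source. Among 10000 lists of other protein-coding genes matched on length and expression the 95% range was -0.10 to -0.03, and 377 had a median as low as -0.10. A general loss of short, abundant mRNAs in ESW libraries may therefore account for the pattern and stays open, beside an effect of ESW on these genes. Spread between libraries stays open too. The list did not pass camera with an estimated correlation (adjusted p = 0.430) or fry (adjusted p = 0.125). The mean log2 CPM of ESW replicate 1 lay above that of Control replicate 1 (8.24 against 8.19).

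In ESW against Control the 6 libraries gave 1003 genes when fitted alone, and the highest of the other 9 splits gave 34; in ESW against CW the values were 1417 and 0, and in CW against Control 16 and 1. In each case 1 of the 10 splits gave as many. For lists the real split gave 11, 11 and 5 and the highest other split 11, 8 and 10, with 2, 1 and 5 of 10 splits as large. With 10 splits no share can fall under 0.1. Of 100 splits of the 9 libraries into 3 groups of 3, 2 gave at least the 1409 genes of the real one. A chance division of these libraries can therefore be excluded at 0.05. A chance difference between cultures cannot, because the 3 libraries of a group may not be separate cultures. The other split, with 1469, kept the 3 ESW libraries together and mixed Control with CW. For genes changed in 1 group against both others, each split was given its largest count over the 3 choices of that group. Here 1 of 100 splits reached 616, the real one, and the next gave 576, from the same mixture. Because the form of this count was chosen after results bearing on it had been seen, chance is not called excluded there.

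Chromosome X was singled out after the called genes were seen, so its counts are given without a test. Of the 22 genes lower in CW against Control 8 lie on it in the gene table, which places 3.49% of the tested genes there; with average transcript length offsets 0 of the lower calls remained, and without CW replicate 3 the fit called 3 lower genes. Among lower genes it was 32 of 483 in ESW against Control and 32 of 587 in ESW against CW, and among genes higher in ESW against Control 14 of 700. The median log2 fold change of the 338 genes of this chromosome with at least 5 CPM was -0.03 in CW against Control, -0.04 in ESW against Control and under 0.01 in size in ESW against CW, and with average transcript length offsets it was -0.01 and -0.03 in the former pair.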
